A study of Mus musculus with 20 samples.

How the data were processed

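Hearts of 20 male mice, 5 per group, were sequenced as poly-A selected, strand-specific libraries on an Illumina HiSeq instrument, and all libraries carry 1 batch label. The FPKM values were made by the authors and deposited as a single table of 25851 genes by 20 libraries. Per the submitters' processing notes HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the mm10 genome, without the role of each. Of the gene identifiers 25826 had a symbol and 25839 a model in GENCODE release M21 on GRCm38. No gene was at 0 in every library and 0 columns belonged to no sample.

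The unit was checked against the values. FPKM times the exon length of each GENCODE gene gave whole multiples of 1 read, within 0.01 reads, in every library for 24971 genes (96.6%), and for 96.2 to 96.4% of the values above 0 of a library. Recovered reads came to 14.2 to 30.4 M per library, and genes without whole reads held 5.36% of them. The effective library sizes behind the FPKM, 14.1 to 31.8 M, followed median-ratio size factors of the recovered reads (ratio 0.992 to 0.998) and not the read totals. So the deposited values were already scaled between libraries and were used without further scaling.

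Genes with a mean FPKM of at least 0.5 over the 20 libraries were tested (13723 genes, with 12128 left out). Group means of log2(FPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3, using 1 fit over the 4 groups with 16 residual degrees of freedom, eBayes with a mean-variance trend, and two-sided tests. Benjamini-Hochberg adjustment was made over all genes tested within each of 5 comparisons, with a threshold of 0.05 on the adjusted p. The comparisons were genotype in sedentary mice, training in wild-type mice, training in labelled knockout mice, genotype in trained mice, and the interaction, which is the training change in labelled knockout minus that in wild-type mice. Ppargc1a and Gdf15 were also tested by exact two-sided permutation, whose smallest p over 252 splits is 0.00794. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

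There were 29 gene lists and 16 lists of cell type markers, and 42 of these had at least 3 measured members and were tested. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over gene lists and over marker lists within each comparison and again with an estimated correlation. Fry, which tests a list against no change and not against other genes, was run as well. For alternative fits camera was run with the preset correlation only. That setting takes the members of a list as nearly independent, so its p does not measure the spread between mice. Overlaps of called genes were set against the number that independent lists share, by a one-sided Fisher's exact test. The pair of comparisons that share the sedentary wild-type libraries was set against 100 simulations of unchanged groups.

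Besides Ppargc1a and Gdf15, the genes named were taken by a rule. From each pairwise comparison it took the 10 largest changes per direction among genes past the threshold with a mean of at least 1 FPKM in the higher group and groups without overlap, and from the interaction the 10 largest per direction. From each list it took up to 4 members past the threshold in order of p, and of these genes the text names a part. Some genes taken by the rule are not reported here. Arntl, Myl7, Adipoq and Ucp1 as library markers were chosen after their values were seen. The groups, comparisons, tests, lists, this rule and the alternatives other than those named next were fixed before the data were examined. Chosen after the data were seen were fits without the 4 libraries with Myl7 above 1000 FPKM, without the 5 libraries with Arntl above 2 FPKM, with log2 Myl7 or log2 Arntl as a covariate, and by limma voom on recovered reads.

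Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter and a mean FPKM of at least 2, median-ratio and TPM scaling, scaling without transcripts of the mitochondrial genome, fits of the groups of a comparison alone, array weights, robust eBayes, the replicate number as a block, and each library left out in turn. The procedure was tested on simulated data with 50 changed genes per fold.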

Results

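Heart RNA was sequenced from 20 male mice aged 14 to 16 weeks, 5 in each of 4 groups. Wild-type mice and mice labelled as a cardiomyocyte knockout of PGC-1α were either sedentary or trained for 6 weeks with access to a running wheel. PGC-1α is the transcriptional coactivator encoded by Ppargc1a that drives mitochondrial biogenesis and oxidative metabolism. The title of the series names suppression of GDF15, a circulating cytokine induced by stress, as the question. Values were deposited as FPKM per gene, from which reads were recovered. Depth was 14.2 to 30.4 M reads per library. Its mean was 20.9 ± 2.94 M in sedentary wild-type, 20.4 ± 4.82 M in sedentary labelled knockout, 17.8 ± 3.38 M in trained wild-type and 22.4 ± 4.75 M in trained labelled knockout hearts. Transcripts of the mitochondrial genome made up 20.3, 17.8, 18.1 and 15.0% of reads in these groups, in the same order. Group values are means ± SD in FPKM with n = 5. Fold changes are log2 values on the log2(FPKM + 0.5) scale with SE. Adjusted p comes from limma over 13723 genes unless another test is named.

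The targeted gene, Ppargc1a (ENSMUSG00000029167, minus strand of chromosome 5, 51454250 to 51567726 in GRCm38, protein coding), was measured first in every library. It was higher, not lower, in the hearts labelled knockout. Sedentary wild-type hearts had 12.3 ± 2.85 FPKM and sedentary labelled knockout hearts 22.9 ± 4.41 FPKM, with all 5 labelled knockout libraries above all 5 wild-type libraries. The difference passed the test (log2 fold change 0.88 ± 0.19, limma adjusted p = 0.00471, exact two-sided permutation p = 0.00794, the smallest that 252 splits can give). After training the level was 15.8 ± 4.86 FPKM in wild-type and 22.6 ± 3.01 FPKM in labelled knockout hearts (log2 fold change 0.55 ± 0.19, limma adjusted p = 0.0387, exact permutation p = 0.0238). The trained difference no longer passed the threshold without the 4 trained libraries that carried atrial transcripts (0.39), without a filter or with the 2 groups fitted alone (0.55 in both), or without any 1 of 6 libraries. Its value was 0.42 without trained wild-type replicate 2, 0.44 without replicate 4, and 0.54, 0.48, 0.57 and 0.54 without trained labelled knockout replicates 1, 2, 3 and 5. Without the 5 libraries with high Arntl, which leaves 1 sedentary wild-type library, the sedentary difference was 1.13 and no longer passed. The deposited value covers all exons of the gene and the deleted part is not stated in the labels, so the level neither backs nor refutes the genotype. The groups are called labelled knockout throughout. Training did not pass the threshold for Ppargc1a in either genotype, with log2 fold changes of 0.33 in wild-type (95% interval -0.07 to 0.73) and -0.01 in labelled knockout hearts (-0.41 to 0.39).

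Gdf15 (ENSMUSG00000038508, minus strand of chromosome 8, 70629393 to 70632456 in GRCm38, protein coding) separated the genotypes without overlap in sedentary and in trained mice. Its level was 1.36 ± 0.615 FPKM in sedentary wild-type against 17.1 ± 4.15 FPKM in sedentary labelled knockout hearts (log2 fold change 3.26 ± 0.35, limma adjusted p = 1.1e-05). After training it was 1.71 ± 0.902 FPKM in wild-type and 31.4 ± 16.6 FPKM in labelled knockout hearts (log2 fold change 3.74 ± 0.35, limma adjusted p = 2.5e-07). The exact two-sided permutation p was 0.00794, the smallest possible, in both. Training itself did not pass the threshold, with log2 fold changes of 0.22 ± 0.35 in wild-type (limma adjusted p = 0.711) and of 0.69 ± 0.35 in labelled knockout hearts (limma adjusted p = 0.153). The interaction was 0.47 ± 0.49 (limma adjusted p = 0.553). Among trained labelled knockout hearts, Gdf15 was 36.0, 44.9 and 48.2 FPKM in replicates 1, 3 and 4, and 15.6 and 12.2 FPKM in replicates 2 and 5, which were the libraries with atrial transcripts. Without the 4 trained libraries of that kind the training change in labelled knockout hearts passed the threshold (1.33), as it did without replicate 5 alone (0.97), with log2 Myl7 as a covariate (0.96) and with array weights (0.92).

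**Figure D1:**
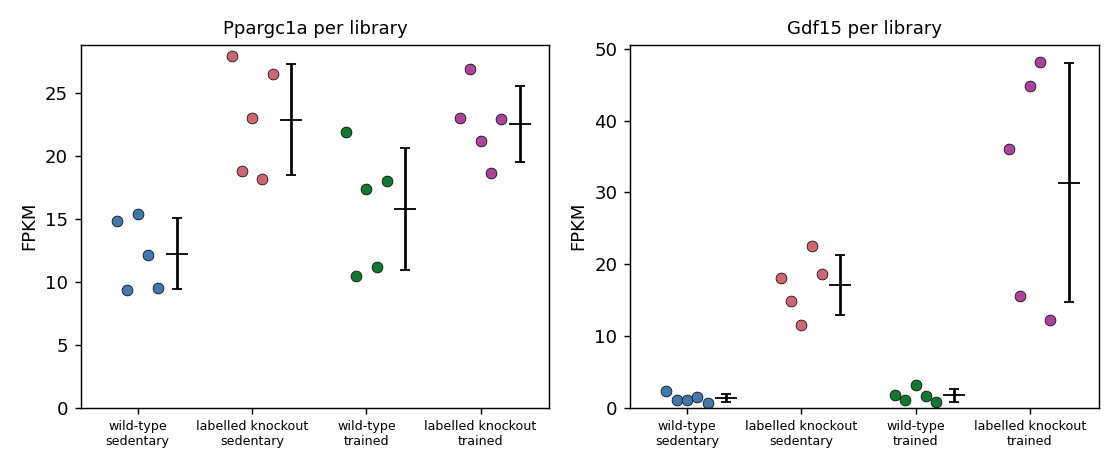
FPKM of Ppargc1a (left) and Gdf15 (right) in each of the 20 libraries by group, with points for libraries and bars for mean ± SD (n = 5). Ppargc1a averaged 12.3 FPKM in sedentary wild-type and 22.9 FPKM in sedentary labelled knockout hearts, and Gdf15 1.36 and 17.1 FPKM.

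Some libraries stood apart from their own group. Arntl, the clock activator also called Bmal1, was at 2.46 to 4.36 FPKM in sedentary wild-type replicates 1 to 4 and 2.50 FPKM in sedentary labelled knockout replicate 1, against 0.0658 FPKM in sedentary wild-type replicate 5 and at most 1.16 FPKM in the remaining libraries. Myl7, the atrial regulatory myosin light chain, was at 1975 and 3484 FPKM in trained wild-type replicates 4 and 5 and at 2055 and 1355 FPKM in trained labelled knockout replicates 2 and 5, and at most 97.1 FPKM elsewhere. The same 4 libraries held the adipocyte gene Adipoq at 3.94 to 36.7 FPKM and the brown adipocyte gene Ucp1 at 4.42 to 117 FPKM. These genes belong to the clock and marker lists, and they were singled out after their values were seen. The first 3 principal components of the log2 values held 30.9, 18.5 and 12.7% of the variance.

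**Figure D2:**
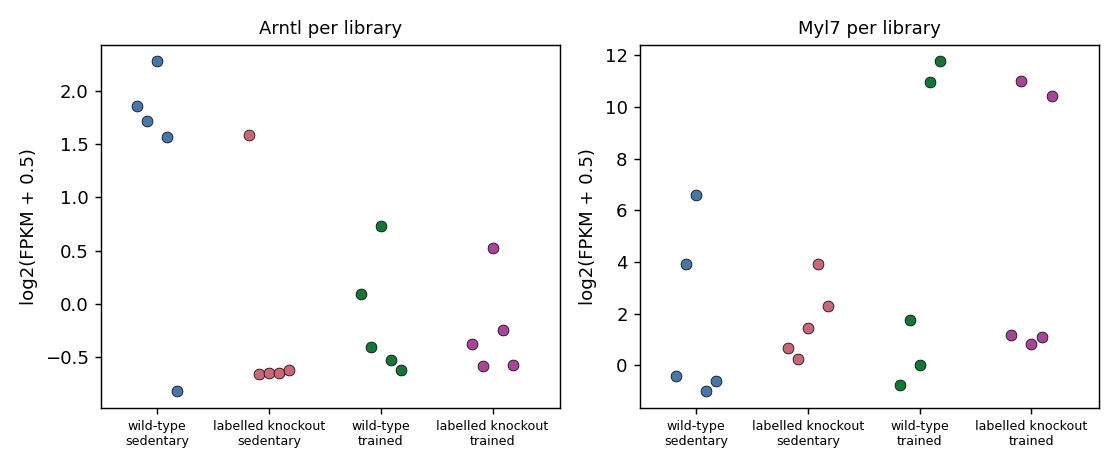
Arntl (left) and Myl7 (right) in each of the 20 libraries as log2(FPKM + 0.5), by group. The 5 libraries with Arntl above 2 FPKM are 4 sedentary wild-type and 1 sedentary labelled knockout, and the 4 libraries with Myl7 above 1000 FPKM are all trained, 2 of each genotype.

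The sedentary genotype comparison asked what differed in labelled knockout hearts without training. Genes of fuel oxidation were lower. Of 20 measured TCA cycle genes 18 fell (20 adjusted over the list alone). Of 22 genes for oxidation of branched-chain amino acids and ketones 20 fell (21 adjusted over the list alone). Of 32 genes for fatty acid uptake and oxidation 18 fell (24 adjusted over the list alone). Bdh1, which interconverts ketone bodies, fell from 28.9 ± 23.1 FPKM in wild-type to 2.51 ± 0.572 FPKM in labelled knockout hearts (log2 fold change -2.89 ± 0.45). Other genes that fell were Ndrg4 (-1.47 ± 0.18) and Fndc5, the precursor of irisin (-1.35 ± 0.14). Acta1, the skeletal α-actin gene of the fetal heart, rose from 415 ± 254 to 2426 ± 448 FPKM (2.85 ± 0.47, limma adjusted p = 5.4e-04). Acta2, smooth muscle actin, rose from 82.6 ± 42.0 to 378 ± 20.3 FPKM (2.32 ± 0.24, limma adjusted p = 9.2e-06).

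The median log2 fold change was -0.42 for the TCA cycle (camera adjusted p = 1.4e-14, adjusted p = 0.0847 with an estimated correlation). It was -0.57 for branched-chain amino acid and ketone oxidation (camera adjusted p = 9.1e-17, adjusted p = 0.0603 with an estimated correlation). It was -0.41 for fatty acid oxidation (camera adjusted p = 2.9e-13, adjusted p = 0.182 with an estimated correlation). Examples were Idh3a (-0.48), a catalytic subunit of isocitrate dehydrogenase, Mpc2 (-0.65) of the mitochondrial pyruvate carrier, Bckdha (-0.81) and Mccc2 (-0.52) of branched-chain amino acid breakdown, and Echs1 (-0.62) and Etfdh (-0.71) of fatty acid oxidation. Respiratory chain subunits that fell were 13 of 36 for complex I (-0.21, camera adjusted p = 4.5e-07, adjusted p = 0.408 with an estimated correlation). They were 8 of 14 for complexes II and III (-0.25, adjusted p = 0.269 with an estimated correlation) and 5 of 15 for complex IV (-0.22, adjusted p = 0.418 with an estimated correlation). Lower too were 8 of 20 for ATP synthase and adenine nucleotide transport, where 1 rose (-0.21, adjusted p = 0.363 with an estimated correlation). Cox7a1, a muscle subunit of complex IV, fell from 698 ± 75.9 to 294 ± 37.3 FPKM and mitochondrial creatine kinase Ckmt2 by 0.76 ± 0.11 on the log2 scale. Among 19 coactivators and partner factors of PGC-1, Esrra (-0.47), Perm1 (-0.57) and the mitochondrial transcription factor Tfam (-0.35) were among 4 that fell, and Ppargc1a itself was the 1 that rose (-0.30, camera adjusted p = 0.00235, adjusted p = 0.269 with an estimated correlation). With log2 Arntl as a covariate the median was -0.10 and camera did not call the list (adjusted p = 0.115). Of 12 further genes linked to PGC-1, 3 fell, among them Fndc5 and Sod2 (-0.67), the mitochondrial superoxide dismutase, and 2 rose. Camera did not call that list in limma (adjusted p = 0.0904).

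Some members of 3 stress-related lists rose in the same hearts, while camera called neither the endoplasmic reticulum stress list (adjusted p = 0.178) nor the heat shock list (adjusted p = 0.123). Of 32 genes of the ATF4 and integrated stress response 6 rose, among them Gdf15, Psat1 of serine synthesis (1.69 ± 0.13) and Sesn2 (0.46), while the list median was 0.14 (camera adjusted p = 2.6e-04, adjusted p = 0.182 with an estimated correlation). The list of 15 p53 targets, which also holds Gdf15, had 6 that rose, with Phlda3 at 1.37 (camera adjusted p = 6.8e-05, adjusted p = 0.0603 with an estimated correlation). Of 18 cardiac stress and fetal genes 6 rose, among them Acta1, Ankrd1 (1.74 ± 0.33) and Tnni1 (1.17), the slow skeletal troponin I (camera adjusted p = 0.00433, adjusted p = 0.354 with an estimated correlation). Of 10 skeletal muscle markers 3 were measured and 3 rose, with fast troponin Tnni2 at 2.00 (camera adjusted p = 0.00133, adjusted p = 0.220 with an estimated correlation), and the sarcoplasmic reticulum pump Atp2a1 rose by 2.19. Krt8 and Krt18, the simple epithelial keratins, rose by 2.51 and 2.38, and the receptor gene Npy4r by 2.42 from 0.200 ± 0.109 FPKM. Angiogenesis and hypoxia genes fell in 7 of 21, with the VEGF receptor Kdr at -0.99 and the apelin receptor Aplnr at -1.08 (camera adjusted p = 8.2e-04, adjusted p = 0.0603 with an estimated correlation). Cell division genes rose in 7 of 17 (camera adjusted p = 2.0e-05, adjusted p = 0.304 with an estimated correlation). Markers of macrophages rose in 5 of 10 (median 0.44, camera adjusted p = 0.00150, adjusted p = 0.704 with an estimated correlation). Those of endothelium fell in 2 of 10 (median -0.20, camera adjusted p = 0.0426, adjusted p = 0.704 with an estimated correlation), and camera did not call them without the 5 libraries with high Arntl (median -0.25, adjusted p = 0.0605).

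In all, 955 genes rose and 867 fell at a limma adjusted p below 0.05, of which 121 and 67 changed at least 2-fold. The groups also differed in how many libraries had high Arntl, 4 of 5 against 1 of 5. With log2 Arntl as a covariate 272 genes rose and 322 fell, of which 249 and 282 were among those above. Of the lists, 8 of 20 TCA cycle, 15 of 22 branched-chain and ketone, 8 of 32 fatty acid and 3 of 36 complex I genes fell, at medians of -0.39, -0.46, -0.42 and -0.25 (camera adjusted p = 1.3e-15, 2.8e-18, 2.5e-14 and 4.4e-11). Without the 5 libraries with high Arntl, which leaves 1 wild-type library, 10 rose and 9 fell. The medians of those lists, in that order, were -0.39, -0.47, -0.43 and -0.33. Rescaled to a common sum (TPM), the split was 1094 up and 402 down, and array weights gave 2630 and 2706. Single libraries moved the counts by over 1.5 times: 609 and 576 without sedentary wild-type replicate 1, 580 and 572 without replicate 3, 606 and 551 without labelled knockout replicate 4, 627 up without replicate 5 and 1435 down without replicate 1.

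The wild-type training comparison asked what 6 weeks of wheel running changed in hearts of wild-type mice. Some heat shock and immediate early genes were higher in trained hearts. Of 15 heat shock genes 8 rose (9 adjusted over the list alone), with the co-chaperones Dnajb1 at 1.37 ± 0.28 and Dnaja1 going from 8.06 ± 2.20 to 20.4 ± 6.94 FPKM. The list median was 0.38 (camera adjusted p = 3.1e-08, adjusted p = 0.353 with an estimated correlation). Hspa1a and Hspa1b, near-identical copies that share reads and are therefore uncertain one by one, rose from 0.969 ± 0.529 to 42.3 ± 33.8 and from 1.27 ± 0.730 to 58.2 ± 48.0 FPKM. Of 20 immediate early genes 7 rose (16 adjusted over the list alone), among them the nuclear receptors Nr4a1 (2.35 ± 0.45, limma adjusted p = 0.0111) and Nr4a3 (2.14 ± 0.35, limma adjusted p = 0.00395). The list median was 0.60 (camera adjusted p = 2.4e-10, adjusted p = 0.343 with an estimated correlation).

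Of the ATF4 and integrated stress response list 7 of 32 rose and 1 fell, with Atf3 at 2.15, Ddit3 at 0.68 and Atf4 at 0.47 (camera adjusted p = 6.7e-04, adjusted p = 0.353 with an estimated correlation). Other genes that rose were Olfml2b (1.49), the kinase Sik1 (1.31) and the galectin Lgals3 (2.08). Epicardial and mesothelial markers had a median of 1.37, with 1 of 8 past the threshold, Wt1 (1.11 ± 0.13, limma adjusted p = 3.1e-04), and 8 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.462 with an estimated correlation). Trained replicates 2, 4 and 5 stood apart in this list, with Upk3b at 14.7, 18.9 and 9.43 FPKM against 0.198 and 0.884 FPKM in replicates 1 and 3. Fatty acid uptake and oxidation genes fell in 11 of 32 (22 adjusted over the list alone), among them lipoprotein lipase Lpl (-0.48), Hadhb (-0.47) and the pyruvate dehydrogenase kinase Pdk4 (-1.01). The median was -0.32 (camera adjusted p = 7.2e-09, adjusted p = 0.400 with an estimated correlation). In the branched-chain and ketone list 6 of 22 fell, Acat1 by 0.36 on the log2 scale (camera adjusted p = 6.6e-07, adjusted p = 0.400 with an estimated correlation). In the TCA cycle 3 of 20 fell (camera adjusted p = 8.0e-05, adjusted p = 0.416 with an estimated correlation). By limma 0 of 10 cardiomyocyte markers passed, with 0 higher and 3 lower at an unadjusted p below 0.05 (median -0.17, camera adjusted p = 0.0389, adjusted p = 0.462 with an estimated correlation). Complex I had 1 of 36 that fell, at a median of -0.05 that was 0.03 after TPM scaling, and camera in limma did not call the list (adjusted p = 0.315). Camera called 6 other lists downward. They were complexes II and III (median -0.09, camera adjusted p = 0.0494, adjusted p = 0.648 with an estimated correlation), mitochondrial gene expression (-0.10, camera adjusted p = 0.00110, adjusted p = 0.474 with an estimated correlation) and transcripts of the mitochondrial genome (-0.40, camera adjusted p = 9.9e-04, adjusted p = 0.431 with an estimated correlation). The others were contractile genes (-0.22, camera adjusted p = 9.9e-04, adjusted p = 0.416 with an estimated correlation), mitochondrial chaperones (-0.16, camera adjusted p = 0.00404, adjusted p = 0.416 with an estimated correlation) and endoplasmic reticulum stress (-0.14, camera adjusted p = 0.0494, adjusted p = 0.648 with an estimated correlation). Of these it called only the mitochondrial genome list without the 4 libraries with atrial transcripts (adjusted p = 0.0373). By limma 0 of 39 matrix genes passed, with 7 higher and 0 lower at an unadjusted p below 0.05 (median 0.21, camera adjusted p = 0.0174, adjusted p = 0.683 with an estimated correlation). Inflammatory cytokine genes rose in 1 of 15 (median 0.33, camera adjusted p = 0.0174, adjusted p = 0.416 with an estimated correlation). On the TPM scale camera called neither the matrix (adjusted p = 0.0551) nor the inflammatory list (0.0553). Among markers of other cell types camera called those of fibroblasts (median 0.23, adjusted p = 0.0389), endothelium (0.16, adjusted p = 0.0395), endocardium and lymphatics (0.51, adjusted p = 0.0389), Schwann and neural cells (0.39, adjusted p = 0.0157) and erythroid cells (1.26, adjusted p = 0.0157) upward, each at an adjusted p of 0.462 with an estimated correlation. Without the 4 libraries with atrial transcripts it still called endothelium (adjusted p = 0.00810) and erythroid cells (adjusted p = 0.0127). It called neither without the 5 libraries with high Arntl (adjusted p = 0.141 and 0.642). Nor did it call endothelium with log2 Arntl as a covariate (0.0772) or on the TPM scale (0.0603), or erythroid cells with log2 Myl7 as a covariate (0.0527). The globin gene Hba-a1 stood at 288 ± 202 FPKM in sedentary and 597 ± 139 FPKM in trained hearts. Single genes that fell were the potassium channel subunit Kcne1 (-1.06), the fractalkine receptor Cx3cr1 (-1.02), Rrad (-0.90), the thioesterase Acot1 (-0.90), the ubiquitin ligase Trim63 (-0.56) and mitochondrial mt-Nd3 (-2.03). Of 18 circadian clock genes 4 rose, with Per2 at 2.52, Ciart at 1.99 and Per1 at 1.44 (camera adjusted p = 0.0230, adjusted p = 0.400 with an estimated correlation). Camera did not call the clock list without the 4 libraries with atrial transcripts (adjusted p = 0.0612), without the 5 with high Arntl (0.488) or with log2 Arntl as a covariate (0.554). Arntl was at 2.56 ± 1.57 FPKM in sedentary and 0.465 ± 0.423 FPKM in trained hearts.

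With training in wild-type hearts 403 genes rose and 347 fell at a limma adjusted p below 0.05, 50 and 18 of them at least 2-fold. Atrial markers had a median of 2.02, adipocyte markers of 1.70 and brown adipocyte markers of 0.23, and trained replicates 4 and 5 held the atrial transcripts. Without the 4 libraries with atrial transcripts 33 genes rose and 6 fell, of which 31 and 5 were shared. Of the lists, 1 of 15 heat shock, 2 of 20 immediate early and 1 of 32 stress response genes rose, at medians of 0.36, 0.46 and 0.21 (camera adjusted p = 2.6e-07, 2.7e-09 and 9.5e-04). There limma called 0 of 32 fatty acid, 0 of 22 branched-chain and ketone and 0 of 20 TCA cycle genes, with 11, 7 and 3 lower at an unadjusted p below 0.05. Their medians went to -0.19, -0.18 and -0.11 (camera adjusted p = 1.9e-05, 1.9e-05 and 0.0274), and that of the cardiomyocyte markers to -0.06 (camera adjusted p = 0.520). With log2 Arntl as a covariate 44 rose and 29 fell, of which 41 and 20 were shared. Of the lists, 5 of 15 heat shock and 1 of 20 immediate early genes rose, at medians of 0.52 and 0.41 (camera adjusted p = 4.6e-12 and 1.4e-07). Limma called 0 fatty acid, 0 branched-chain and ketone and 0 TCA cycle genes (16, 8 and 5 lower at an unadjusted p below 0.05), at medians of -0.27, -0.20 and -0.17 (camera adjusted p = 1.7e-09, 1.6e-05 and 2.3e-04). The fit of these 2 groups alone gave 52 up and 9 down, the TPM scale 193 and 56, leaving out the mitochondrial genome 167 and 250, no filter 208 and 146, and log2 Myl7 as a covariate 299 and 160, while array weights gave 1221 and 1418. Without the 5 libraries with high Arntl 1 rose and 3 fell, and Per1 and Ciart stood at -0.04 and -0.62, against the direction above. Counts without 1 library were 118 and 72 (sedentary replicate 1), 215 and 164 (sedentary 2), 128 and 70 (sedentary 3), 1051 and 1260 (trained 1), 147 and 88 (trained 2), 94 and 33 (trained 4), and 164 and 90 (trained 5).

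In labelled knockout hearts nuclear genes of the respiratory chain fell with training and those of the extracellular matrix rose. The sample labels used here give weeks of training but no distance run, so equal running in both genotypes was not shown. That limit holds for the interaction as well. Of 36 complex I subunits 35 fell, of 14 complex II and III subunits 14, of 15 complex IV subunits 13 and of 20 ATP synthase and adenine nucleotide transport genes 19. Ndufs3 of complex I fell from 127 ± 5.99 to 75.3 ± 3.90 FPKM (-0.76 ± 0.07, limma adjusted p = 3.1e-06) and Cox7a1 from 294 ± 37.3 to 129.7 ± 23.7 FPKM (-1.19 ± 0.14, limma adjusted p = 1.1e-05). Of 39 matrix and fibrosis genes 34 rose (36 adjusted over the list alone), with the protease inhibitor Timp1 going from 3.73 ± 0.748 to 37.7 ± 20.1 FPKM (2.99 ± 0.36) and the matricellular gene Postn from 5.51 ± 1.49 to 48.9 ± 36.7 FPKM (2.66 ± 0.42).

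The median log2 fold change was -0.66 for complex I (camera adjusted p = 1.5e-25, adjusted p = 0.0715 with an estimated correlation) and -0.61 for complexes II and III (camera adjusted p = 3.7e-13, adjusted p = 0.0715 with an estimated correlation). It was -0.66 for complex IV (camera adjusted p = 3.9e-10, adjusted p = 0.0993 with an estimated correlation) and -0.64 for ATP synthase and nucleotide transport (camera adjusted p = 8.2e-17, adjusted p = 0.0715 with an estimated correlation). Further examples were Ndufa9 (-0.69), the Rieske protein gene Uqcrfs1 (-0.69) and the heart adenine nucleotide translocase Slc25a4 (-0.82). Of 33 genes for expression of the mitochondrial genome 27 fell (median -0.50, camera adjusted p = 1.5e-17, adjusted p = 0.0715 with an estimated correlation). Of 13 transcripts of that genome 6 fell (median -0.49, camera adjusted p = 0.00537, adjusted p = 0.399 with an estimated correlation). The TCA cycle had 19 of 20 that fell, with Mdh2 at -0.68 and Pdhb at -0.63 (median -0.52, camera adjusted p = 4.8e-14, adjusted p = 0.0715 with an estimated correlation). In the branched-chain and ketone list 20 of 22 fell, with Mccc2 at -0.69 (camera adjusted p = 7.1e-12, adjusted p = 0.0715 with an estimated correlation). In fatty acid oxidation 25 of 32 fell, with Eci1 at -0.92 and Echs1 at -0.70, while 1 rose (camera adjusted p = 3.7e-13, adjusted p = 0.0992 with an estimated correlation). Lactate dehydrogenase Ldhb, listed with glycolysis, fell by 0.95 on the log2 scale. Contractile and calcium handling genes fell in 11 of 25, with cardiac troponin I Tnni3 at -0.93 (median -0.32, camera adjusted p = 2.0e-04, adjusted p = 0.179 with an estimated correlation). The muscle genes Smco1 (-1.31) and Tnni2 (-1.38) fell as well. Cardiomyocyte markers, 7 of which the contractile list also holds, fell in 8 of 10 (median -0.62, camera adjusted p = 1.8e-06, adjusted p = 0.130 with an estimated correlation).

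The matrix list had a median of 1.30 (camera adjusted p = 1.7e-24, adjusted p = 0.0715 with an estimated correlation), with the fibrillar collagens Col1a1 at 1.59 and Col1a2 at 1.43, Col6a2 at 1.06, thrombospondin Thbs1 at 2.19 and cartilage oligomeric matrix protein Comp at 3.36. Fibroblast markers, 3 of which are shared with the matrix list, rose in 7 of 10, with Lum at 1.00 (median 0.89, camera adjusted p = 5.6e-07, adjusted p = 0.106 with an estimated correlation). Macrophage markers rose in 10 of 10, with Adgre1 at 1.29 and Csf1r at 0.72 (median 0.73, camera adjusted p = 5.6e-07, adjusted p = 0.171 with an estimated correlation). By each library's mean log2 value, the matrix list stood at 4.38, 4.64 and 4.98 in trained replicates 1, 3 and 4. It was 3.71 and 3.91 in replicates 2 and 5, with atrial transcripts, and 2.77 to 3.10 in sedentary labelled knockout hearts. The macrophage list stood at 4.83, 4.86 and 4.93, at 4.17 and 4.34, and at 3.70 to 3.88, in that order. By limma 0 of 10 endothelial markers passed, with 0 higher and 1 lower at an unadjusted p below 0.05 (median -0.02, 0.25 after TPM scaling). Inflammatory cytokine genes rose in 8 of 15, with the chemokine Ccl8 at 3.25 ± 0.40 (camera adjusted p = 5.4e-05, adjusted p = 0.0715 with an estimated correlation). The acute-phase gene Serpina3n rose from 8.15 ± 1.37 to 83.4 ± 50.8 FPKM. Immediate early genes rose in 9 of 20, with Fosl2 at 1.28 and Junb at 1.42 (camera adjusted p = 6.6e-06, adjusted p = 0.141 with an estimated correlation). The integrated stress response list had 11 that rose, with asparagine synthetase Asns at 1.04 and Pycr1 at 0.84, and 2 that fell (camera adjusted p = 0.00339, adjusted p = 0.163 with an estimated correlation). Cardiac stress and fetal genes rose in 5 of 18, with slow myosin Myh7 at 1.53 and Fhl1 at 1.07 (camera adjusted p = 0.00121, adjusted p = 0.179 with an estimated correlation). Lgals3 (2.68) and Igf1 (1.04) rose too.

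With training in labelled knockout hearts 1656 genes rose and 2236 fell at a limma adjusted p below 0.05, 202 and 63 at least 2-fold. Without the 4 libraries with atrial transcripts 1750 rose and 2186 fell, with 35 of 36 complex I genes lower and 36 of 39 matrix genes higher. The balance of higher and lower genes rested on the scale. After TPM scaling, 4337 rose and 640 fell with the median of all genes at 0.23 instead of -0.02, and without the mitochondrial genome 3127 and 904. Array weights gave 2790 and 3490. On the TPM scale 33 of 36 complex I genes fell (median -0.39) and 38 of 40 matrix genes rose.

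**Figure D3:**
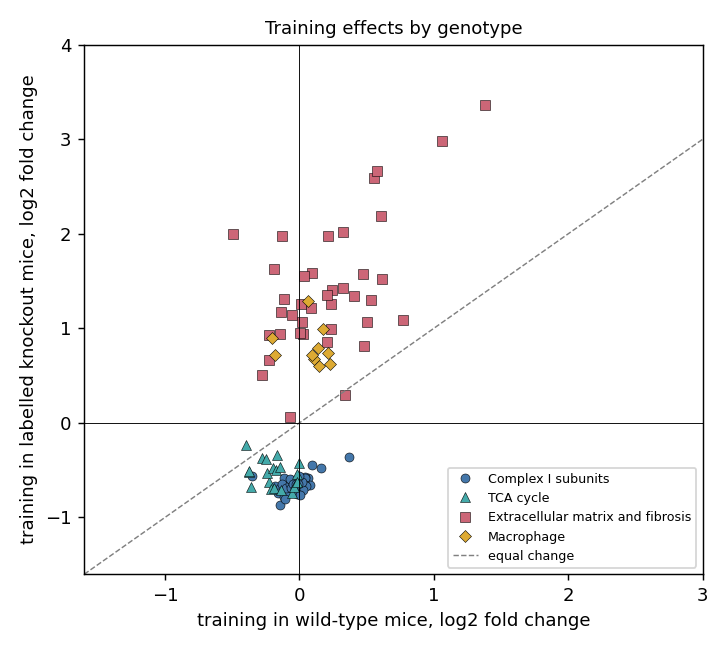
Log2 fold change with training in wild-type hearts (horizontal) and in labelled knockout hearts (vertical) for the members of 4 lists, 1 point per gene, with a dashed line of equal change. The median of complex I was -0.05 in wild-type (0.03 after TPM scaling) and -0.66 in labelled knockout hearts, and that of the matrix list 0.21 and 1.30.

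The genotype comparison among trained mice asked what distinguished labelled knockout from wild-type hearts after running. Oxidative genes were lower across the respiratory chain and fuel oxidation. This held for complex I in 36 of 36 members, complexes II and III in 14 of 14, complex IV in 13 of 15 and ATP synthase and nucleotide transport in 19 of 20. It also held for the TCA cycle in 19 of 20, branched-chain and ketone oxidation in 22 of 22 and fatty acid oxidation in 26 of 32. Cox7a1 stood at 615 ± 120.3 FPKM in wild-type and 129.7 ± 23.7 FPKM in labelled knockout hearts (-2.24 ± 0.14, limma adjusted p = 3.3e-09). Matrix genes were higher in 34 of 39 and cardiac stress and fetal genes in 11 of 18. Cilp, which encodes cartilage intermediate layer protein (chromosome 9, 65265180 to 65280605, plus strand), stood at 2.78 ± 2.28 FPKM in wild-type and 47.4 ± 32.3 FPKM in labelled knockout hearts (3.76 ± 0.52, limma adjusted p = 1.9e-05).

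In this comparison 5 lists held with an estimated correlation. They were complexes II and III (median -0.74, camera adjusted p = 6.6e-16, adjusted p = 0.0424 with an estimated correlation), ATP synthase and nucleotide transport (-0.79, camera adjusted p = 4.8e-20, adjusted p = 0.0454 with an estimated correlation) and the TCA cycle (-0.76, camera adjusted p = 2.4e-19, adjusted p = 0.0424 with an estimated correlation). The others were branched-chain and ketone oxidation (-0.79, camera adjusted p = 7.8e-19, adjusted p = 0.0424 with an estimated correlation) and mitochondrial gene expression, where 28 of 33 were lower (-0.51, camera adjusted p = 8.7e-19, adjusted p = 0.0424 with an estimated correlation). Complex I had a median of -0.81 (camera adjusted p = 5.4e-31, adjusted p = 0.0576 with an estimated correlation) and complex IV of -0.84 (camera adjusted p = 2.4e-14, adjusted p = 0.0581 with an estimated correlation). Fatty acid oxidation had a median of -0.73 (camera adjusted p = 1.6e-15, adjusted p = 0.0667 with an estimated correlation). Named members were Ndufs3 (-0.88), Atp5g1 (-1.13), Mpc2 (-1.34), Suclg1 (-1.10), Bckdhb (-1.35), Mccc2 (-0.98), Bdh1 (-2.34) and Echs1 (-1.06). Fndc5 (-1.97), the glutathione transferase Gstk1 (-2.03), Rpl3l (-1.91), Tnni3 (-1.57), Esrra (-0.85), Perm1 (-0.78), the angiogenic factor Vegfb (-0.77) and the potassium channel subunit Kcnip2 (-0.50) were lower as well. The contractile list as a whole had 8 of 25 lower, with a median of -0.24 that was 0.03 after TPM scaling (camera adjusted p = 0.00368, adjusted p = 0.297 with an estimated correlation).

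The matrix list had a median of 1.33 (camera adjusted p = 8.8e-22, adjusted p = 0.0576 with an estimated correlation), with Thbs4 at 3.21, Timp1 at 2.95 and Ltbp2 at 2.94. Among the fetal genes were Acta1 (3.52), Ankrd1 (2.45), Myh7 (2.21) and the natriuretic peptide Nppa (3.38), which is also an atrial marker and ranged widely among trained wild-type hearts (1426 ± 1962 FPKM) (camera adjusted p = 2.3e-06, adjusted p = 0.0667 with an estimated correlation). Cell division genes were higher in 15 of 17, at low levels, with Top2a at 0.330 ± 0.159 and 1.06 ± 0.385 FPKM (0.90) and Tpx2 at 0.99 (camera adjusted p = 8.3e-08, adjusted p = 0.119 with an estimated correlation). The integrated stress response list had 12 of 32 higher and 1 lower, with the folate enzyme Mthfd2 at 1.26 (camera adjusted p = 0.00199, adjusted p = 0.121 with an estimated correlation). Macrophage markers were higher in 10 of 10, with Adgre1 at 1.47 and Csf1r at 1.09 (median 1.10, camera adjusted p = 1.6e-09, adjusted p = 0.117 with an estimated correlation). Fibroblast markers were higher in 8 of 10, with Lum at 1.12 (median 0.67, camera adjusted p = 5.0e-06, adjusted p = 0.117 with an estimated correlation). Endothelial markers were lower in 6 of 10, with Tie1 at -0.64 (median -0.45, camera adjusted p = 0.00149, adjusted p = 0.213 with an estimated correlation). Cardiomyocyte markers were lower in 8 of 10 (median -0.46, camera adjusted p = 1.5e-04, adjusted p = 0.213 with an estimated correlation). Serpina3n (3.09) was higher.

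In trained mice 1713 genes were higher and 2112 lower in labelled knockout hearts at a limma adjusted p below 0.05, 267 and 175 by at least 2-fold. Without the 4 libraries with atrial transcripts the counts were 1608 and 1939. After TPM scaling 5453 were higher and 813 lower with the median of all genes at 0.26, and without the mitochondrial genome 4159 and 1001. On the TPM scale 32 of 36 complex I genes were lower and 37 of 40 matrix genes higher.

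The interaction tested whether training moved a gene differently in labelled knockout than in wild-type hearts. The training change of complex I subunits was lower in labelled knockout hearts in 34 of 36 (median -0.63, camera adjusted p = 2.1e-27, adjusted p = 0.111 with an estimated correlation). It was lower for ATP synthase and nucleotide transport in 19 of 20 (median -0.60, camera adjusted p = 4.2e-18, adjusted p = 0.111 with an estimated correlation), for complex IV in 13 of 15 (median -0.58, camera adjusted p = 5.4e-12, adjusted p = 0.135 with an estimated correlation) and for complexes II and III in 12 of 14 (median -0.55, camera adjusted p = 1.0e-11, adjusted p = 0.111 with an estimated correlation). Atp5g1, of the proton-carrying ring of ATP synthase, was at 172 and 175 FPKM in sedentary and trained wild-type hearts and at 132 and 79.5 FPKM in labelled knockout hearts (interaction -0.75 ± 0.10, limma adjusted p = 0.00462). Matrix genes moved higher in 24 of 39 (median 1.13, camera adjusted p = 1.3e-20, adjusted p = 0.111 with an estimated correlation), with Col3a1 at 28.4 and 26.7 FPKM in wild-type against 26.7 and 122 FPKM in labelled knockout hearts (2.11 ± 0.43, limma adjusted p = 0.00947). In trained labelled knockout hearts Col3a1 was 142, 170 and 192 FPKM in replicates 1, 3 and 4. It was 51.8 and 55.7 FPKM in replicates 2 and 5, the libraries with atrial transcripts.

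The TCA cycle moved lower in 10 of 20 (camera adjusted p = 1.9e-08, adjusted p = 0.226 with an estimated correlation). Mitochondrial gene expression moved lower in 17 of 33 (camera adjusted p = 3.4e-12, adjusted p = 0.111 with an estimated correlation). Fatty acid oxidation and the branched-chain and ketone list moved lower in 6 of 32 (adjusted p = 0.405 with an estimated correlation) and 6 of 22 (adjusted p = 0.289 with an estimated correlation). By limma 0 of 13 transcripts of the mitochondrial genome passed, with 0 higher and 0 lower at an unadjusted p below 0.05 (median -0.18, 0.01 after TPM scaling, camera adjusted p = 0.850). Named genes were Ndufs3 (-0.66), Uqcrfs1 (-0.59), Cox5a (-0.51), Cox7a1 (-0.99), the mitochondrial ribosomal gene Mrpl4 (-0.59), Mdh2 (-0.64), Mpc2 (-0.68), Ldhb (-0.72), Tnni3 (-0.96) and Esrra (-0.37). The interaction was positive for Cilp (2.93), Ccl8 (2.54), Fbn1 (2.49), the lubricin gene Prg4 (2.26 ± 0.32, limma adjusted p = 0.00462) and Postn (2.08). It was positive as well for Ltbp2 (2.03), Timp1 (1.93), Thbs1 (1.58), Col1a1 (1.49), Myh7 (1.47), Fhl1 (0.77) and Pycr1 (0.67). Macrophage markers moved higher in 3 of 10, with Adgre1 at 1.22 (camera adjusted p = 6.6e-06, adjusted p = 0.245 with an estimated correlation). Fibroblast markers moved higher in 3 of 10 (camera adjusted p = 1.3e-04, adjusted p = 0.245 with an estimated correlation). Cardiomyocyte markers moved lower in 3 of 10 (camera adjusted p = 1.6e-04, adjusted p = 0.245 with an estimated correlation). Arrdc2 (-2.36) and Depp1 (-1.99) moved lower, at 24.7 and 65.1 FPKM in sedentary and trained wild-type against 59.2 and 39.3 FPKM in labelled knockout hearts for Depp1.

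The interaction called 319 genes higher and 686 lower at a limma adjusted p below 0.05. High Arntl fell mostly on sedentary wild-type libraries. With log2 Arntl as a covariate the counts were 83 and 184, of which 73 and 179 were shared. Of the lists, 19 of 36 complex I genes were lower and 11 of 39 matrix genes higher, and the complex I median was -0.57. On the TPM scale the split was 230 and 31, with the median of all genes at 0.17. There 4 of 36 complex I genes were lower at a median of -0.44, while 19 of 40 matrix genes were higher. Without the mitochondrial genome the counts were 474 and 45, without a filter 204 and 425, with array weights 2380 and 2661 and without the 4 libraries with atrial transcripts 497 and 800. Without the 5 libraries with high Arntl, which leaves 1 sedentary wild-type library, limma called 1 gene higher and 0 lower, where 422 and 742 had an unadjusted p below 0.05. There the complex I median was -0.50 and that of the matrix list 0.93. Genes higher without 1 library at a time were 138, 133, 185 and 532 for sedentary wild-type replicates 1, 2, 3 and 5, 611, 208, 144, 202 and 185 for sedentary labelled knockout replicates 1 to 5, 163 for trained wild-type replicate 3, and 143, 119, 133 and 484 for trained labelled knockout replicates 1, 3, 4 and 5. Genes lower were 366, 359, 403 and 1075 for sedentary wild-type replicates 1, 2, 3 and 5, 1087, 343 and 437 for sedentary labelled knockout replicates 1, 3 and 4, 401 for trained wild-type replicate 3, and 386, 361 and 371 for trained labelled knockout replicates 1, 3 and 4.

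**Figure D4:**
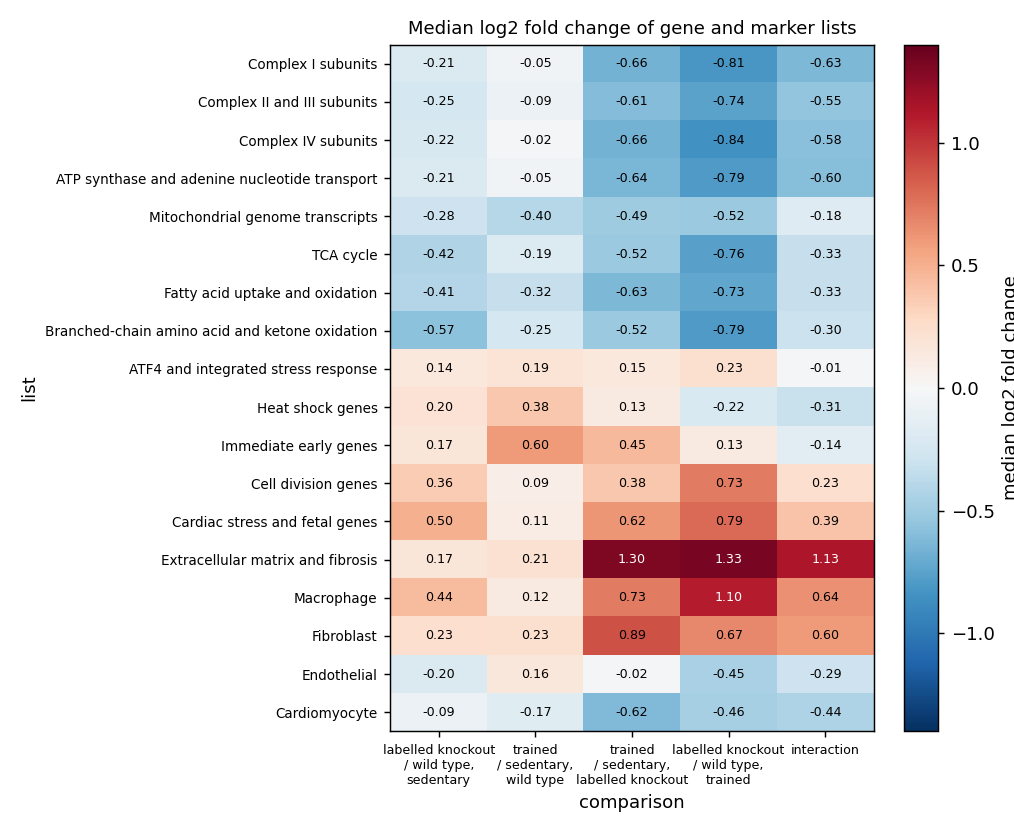
Median log2 fold change, on the log2(FPKM + 0.5) scale, of the measured members of 18 lists (vertical) in the 5 comparisons (horizontal), with the value printed in each cell and red for higher and blue for lower. Complex I goes from -0.21 in the sedentary to -0.81 in the trained genotype comparison, while the signs of complexes I and IV and ATP synthase in wild-type training, cardiomyocyte markers in the sedentary and heat shock genes in the trained genotype comparison, endothelial markers in labelled knockout training, and stress response, immediate early and mitochondrial genome lists in the interaction turn after TPM scaling.

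Many of the same genes were called with training in both genotypes. Of these 207 rose in both, where independent lists would share 48.6, and 180 fell in both, where they would share 56.5 (one-sided Fisher's exact p = 8.1e-86 and 3.2e-54). That test takes genes, which vary together, as independent units, so its p does not measure the spread between mice. Opposite calls were made for 3 genes in each direction. Across the 13723 genes, which are not independent replicates, the training changes had a Pearson r of 0.422, and of 0.233 without the 4 libraries with atrial transcripts, 0.547 with log2 Arntl as a covariate and 0.551 without the 5 libraries with high Arntl. Genes called up in labelled knockout hearts had a median of 0.53 there and 0.18 in wild-type hearts, and those called down -0.43 and -0.10. The shared count was 23 without the 4 libraries with atrial transcripts, 56 with Arntl as a covariate, 163 after TPM scaling and 3 without the 5 libraries with high Arntl. It was 195 without the mitochondrial genome, 167 without a filter, 256 with log2 Myl7 as a covariate and 836 with array weights. Without 1 library it was 113, 231 and 112 (sedentary wild-type 1, 2 and 3), 252, 247 and 251 (sedentary labelled knockout 2, 4 and 5), 907, 129, 71 and 136 (trained wild-type 1, 2, 4 and 5) and 257 (trained labelled knockout 3). The genotype comparisons in sedentary and trained mice shared 469 genes up (119 for independent lists) and 573 down (133 for independent lists), with 5 and 4 opposite calls and an r of 0.487 across genes. Those shared genes came to 18 without the 5 libraries with high Arntl and 535 with log2 Arntl as a covariate.

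The sedentary genotype and the wild-type training comparisons share the sedentary wild-type libraries. They had 74 genes up in both (28.0 for independent lists) and 86 down in both (21.9 for independent lists), with an r of 0.469 across genes. Unchanged simulated groups set against the same libraries gave an r of 0.503, so r alone does not show a shared response. The simulation shared 0 limma calls on average, which was to be expected, as its genes varied independently and without group changes. The covariance was 0.0532 against 0.0190 in the simulation. With the shared libraries split between the comparisons r was 0.277 on average over 10 splits (0.176 to 0.397). Arntl was high in most of the shared libraries, with log2 fold changes of -1.52 for the sedentary genotype and -1.47 for wild-type training. The simulation lacks that structure and each part of a split keeps libraries with high Arntl. So neither shows a shared response to genotype and training.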

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

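The test of atrial transcripts in all trained hearts, the test by endothelial markers, the interaction part of the clock test, its reading against genes not called, the share of calls kept with the covariate and the counts over other splits of the libraries were chosen after the result was seen, as were the fits without libraries of high Myl7 or Arntl and those with either gene as a covariate. Of 303 values of a named gene in a group that were examined, 14 held a library far from the other 4 of its group by Dixon's test, where chance gives about 1 in 20. In sedentary labelled knockout replicate 3 Ldhb was 914 FPKM (others 766 to 789), Ndufs3 138 FPKM (others 123 to 127), Slc25a4 2348 FPKM (others 1995 to 2072) and Tnni3 1697 FPKM (others 1314 to 1335). In other libraries of that group Per2 was 1.74 FPKM in replicate 1 (others 10.5 to 13.5), Serpina3n 5.85 FPKM in replicate 1 (others 8.28 to 9.47), Fosl2 4.54 FPKM in replicate 2 (others 2.43 to 2.61), Cilp 16.3 FPKM in replicate 4 (others 3.57 to 4.31) and Thbs1 1.14 FPKM in replicate 5 (others 2.03 to 2.27). Ciart was 18.7 FPKM in sedentary wild-type replicate 5 (others 0.929 to 1.99). In trained wild-type hearts Atf3 was 33.7 FPKM in replicate 5 (others 9.46 to 12.8) and Ccl8 3.88 FPKM in replicate 2 (others 0.684 to 1.17). In trained labelled knockout hearts Kcnip2 was 52.8 FPKM in replicate 5 (others 43.3 to 44.4) and Lum 62.6 FPKM in replicate 5 (others 49.3 to 52.6).

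Of 110 named genes, 51 had a training change that differed between the genotypes by the limma interaction, given here as its log2 value. Some were named because they passed this test, so their number does not measure how common such differences were. Of 27 calls of genes named for the interaction, 19 held without any 1 library. With log2 Arntl as a covariate 18 held, and on the TPM scale 17. The training change was lower in labelled knockout hearts for the respiratory chain and energy transfer genes Ndufs3 (-0.66), Ndufa9 (-0.54), Uqcrfs1 (-0.59), Cox7a1 (-0.99), Cox5a (-0.51), Atp5g1 (-0.75), Slc25a4 (-0.64) and Ckmt2 (-0.64). It was lower for the fuel oxidation genes Mpc2 (-0.68), Idh3a (-0.33), Mdh2 (-0.64), Pdhb (-0.40), Suclg1 (-0.61), Mccc2 (-0.46), Bckdhb (-0.73), Echs1 (-0.44), Eci1 (-0.66) and Ldhb (-0.72). It was lower as well for Esrra (-0.37), Sod2 (-0.39), Tnni2 (-1.32), Tnni3 (-0.96), Rpl3l (-1.01), Gstk1 (-1.10), Vegfb (-0.54), Kcnip2 (-0.65), Mrpl4 (-0.59), Arrdc2 (-2.36) and Depp1 (-1.99). It was higher for the matrix genes Timp1 (1.93), Postn (2.08), Thbs1 (1.58), Col6a2 (1.05), Col1a2 (1.11), Col1a1 (1.49), Lum (0.76), Ltbp2 (2.03), Fbn1 (2.49) and Col3a1 (2.11), and for Kcne1 (1.12), Cx3cr1 (1.32), Ccl8 (2.54), Serpina3n (2.05), Adgre1 (1.22), Csf1r (0.63), Igf1 (0.94), Fhl1 (0.77), Myh7 (1.47), Pycr1 (0.67), Cilp (2.93) and Prg4 (2.26).

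Atrial transcripts were high in 4 trained libraries, 2 of each genotype. Of 7 further atrial genes listed before their values were seen 6 were measured, and for 5 of them those 4 libraries were the 4 highest of 20, Sbk3 at 33.5 to 117 FPKM against at most 6.59 FPKM elsewhere. Against training raising these transcripts in all hearts, the median of the other 6 trained libraries lay above the highest sedentary library for 1 of those 6 genes, Pam (95.0 against 90.3 FPKM). Atrial tissue in those heart pieces may be the source, and Adipoq and Ucp1 in the same libraries leave fat tissue open, which was not tested. Whether dissection differed with training cannot be read from the labels.

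Counts of called genes moved with Arntl. Within groups, the Arntl slope was opposite to the change in 82.4% of genes called for wild-type training and in 78.8% of genes called for the sedentary genotype, against 70.2% and 69.5% of genes not called, and had the sign of the change in 81.1% of genes called in the interaction, against 72.0% of genes not called. Since genes not called came close to the same shares, that test does not decide. With log2 Arntl as a covariate 29.1% of the sedentary genotype calls, 25.1% of the interaction calls and 8.13% of the wild-type training calls were kept. This argues against clock phase as the whole cause of the kept calls only as far as Arntl measures it. Clock phase that this 1 gene does not measure stays open for them. For the calls that were lost, clock phase at collection cannot be told apart from an effect of genotype or training. Since Arntl differed between these groups, the covariate also widens the error, so a call can be lost while its effect stays. For the sedentary genotype the TCA cycle and fatty acid medians changed little with the covariate, while fewer members passed. An effect on the clock itself stays open as well, since Arntl was high in 4 of 5 sedentary wild-type and 1 of 5 sedentary labelled knockout libraries and no collection time is given. The split of the sedentary libraries that called the most genes, 2861, parted exactly those 5 libraries from the rest, which points to a structure of the samples beside genotype. Arntl does not describe all of it. The third principal component put sedentary wild-type replicates 1 to 3 at 14.7 to 26.5, and replicates 4, with high Arntl, and 5 at -10.5 and -15.6. Ttn was 36.0 to 49.5 FPKM in replicates 1 to 3, and 22.4 and 23.6 FPKM in replicates 4 and 5. In labelled knockout replicate 1 Ttn was 42.7 FPKM, against 21.3 to 24.2 FPKM in replicates 2 to 5. The source was not tested.

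Complex I transcripts fell more with training in labelled knockout hearts. The scaling of the deposited values is argued against as the whole cause by the median interaction of -0.44 after TPM scaling, where the median of all genes was 0.17. Clock phase, as far as Arntl measures it, is argued against as the whole cause by -0.57 with log2 Arntl as a covariate. A lower share of cardiomyocyte RNA was first tested by contractile genes, whose median of -0.05 (quartiles -0.43 to 0.17) lay apart from that of complex I (-0.63, quartiles -0.68 to -0.57) but went both ways and left it undecided. The test was then replaced by endothelial markers, with a median of -0.29 (quartiles -0.39 to -0.07). That median lay apart from those of fibroblasts (0.60, quartiles 0.35 to 0.92) and macrophages (0.64). More fibroblast and macrophage RNA would lower the endothelial and cardiomyocyte shares together, so that test cannot decide either. Of 10 cardiomyocyte markers 8 were lower and 0 higher in the interaction at an unadjusted limma p below 0.05. By each library's mean log2 value these markers stood at 10.22 to 10.41 in sedentary and 9.87 to 10.33 in trained wild-type hearts. In labelled knockout hearts they stood at 10.15 to 10.28 and at 9.51 to 9.68. A response of labelled knockout hearts to training may remain as a hypothesis, found and tested on the same data. A lower share of cardiomyocyte RNA and more fibroblasts or macrophages stay open. A difference in distance run, which the sample labels used here do not give, stays open too.

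In other splits of the same libraries into groups of the same sizes, 100 with the real one, the share that reached the real count was below 0.05 for each comparison, without adjustment over the 5. For the sedentary genotype, wild-type training and the interaction another split gave more genes than the real one, so chance is not excluded there. For labelled knockout training and the trained genotype no other split examined reached the real count, which argues against chance for these. With the 2 groups of a comparison fitted alone, the sedentary genotype gave 1645 genes, reached in 3 splits, with 2861 as the highest other. Wild-type training gave 61 genes, reached in 3 splits, with 950 as the highest other, in a split that parted sedentary replicates 1 to 4 and trained replicate 1 from the rest, again a structure of the samples. Training in labelled knockout hearts gave 4310 genes against at most 1586 and the trained genotype 3557 against at most 521, each reached in 1 split. The interaction gave 1005 genes, reached in 2 splits of the training labels within genotype, with 1087 as the highest other.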

How the results depend on the processing

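Fits without the libraries of high Myl7 or Arntl, those with either gene as a covariate and voom on recovered reads were chosen after the result was seen, and the cause of the changes below was not tested except where named. Of 155 calls of named genes, 155 held with a pseudocount of 1, 153 with 0.1, 155 with median-ratio scaling, 155 with robust eBayes, 136 with TPM scaling, 136 without a filter, 131 without any 1 library and 120 with log2 Arntl as a covariate. In the comparisons they touch, 102 of 124 calls held without the 4 libraries with atrial transcripts and 40 of 121 without the 5 libraries with high Arntl. The comparisons differed in this. For wild-type training 14 of 28 calls held without any 1 library, 8 with log2 Arntl as a covariate and 7 without the libraries with atrial transcripts. For the interaction 19, 18 and 26 of 27 held, in that order. For labelled knockout training 35 of 35 held in each of these fits. Gdf15 was higher in labelled knockout hearts by 3.13 to 3.43 (sedentary) and 3.53 to 4.02 (trained) without any 1 library.

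Array weights raised the counts to 2630 up and 2706 down for the sedentary genotype, 1221 and 1418 for wild-type training, 2790 and 3490 for labelled knockout training and 2380 and 2661 for the interaction, with 836 genes shared by the training comparisons and Gdf15 at 0.92 and past the threshold for labelled knockout training. With the replicate block wild-type training gave 804 and 860, with 687 shared, although the labels do not say what the numbers mark and they were not taken as pairs: 12 of 30 pairs with the same number had residuals correlated above 0.1 (-0.278 to 0.484), and in 9 the own number correlated best. All 6 pairs of number 1 lay above 0.1 (0.251 to 0.364), against 0, 1, 2 and 3 of 6 for numbers 2 to 5, so a structure shared by libraries of number 1 stays open. TPM scaling gave 402 down for the sedentary genotype, 193 and 56 for wild-type training, 4337 and 640 for labelled knockout training, 5453 and 813 for the trained genotype and 31 down for the interaction, with 163 shared. Without the mitochondrial genome wild-type training gave 167 up, labelled knockout training 3127 and 904, the trained genotype 4159 and 1001 and the interaction 45 down, with 195 shared. Both scalings divide each library by its own sum, which by construction moves all genes of a library together. Without a filter wild-type training gave 208 and 146 and the interaction 204 and 425, with 167 shared, and Ppargc1a in trained mice was at 0.55 and no longer passed, as more genes were tested. With the groups of a comparison fitted alone, which leaves fewer libraries, wild-type training gave 52 and 9, and Ppargc1a in trained mice was at 0.55 and no longer passed.

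Without the 5 libraries with high Arntl the sedentary genotype gave 10 and 9, wild-type training 1 and 3, the interaction 1 and 0 by limma (422 and 742 at an unadjusted p below 0.05), the shared training genes 3 and the shared genotype genes 18. Ppargc1a in sedentary mice was at 1.13 and no longer passed, 5 marker lists passed for wild-type training, and Per1 (-0.042) and Ciart (-0.62) turned direction there. That fit has 1 sedentary wild-type library, which is assumed to vary like the other groups, so fewer libraries are a cause. With log2 Arntl as a covariate the counts were 272 and 322 (sedentary genotype), 44 and 29 (wild-type training) and 83 and 184 (interaction), with 56 shared by the training and 535 by the genotype comparisons. Without the 4 libraries with atrial transcripts wild-type training gave 33 and 6 with 3 marker lists, and the interaction 497 up, with 23 shared, Ppargc1a in trained mice at 0.39 and not past the threshold, and Gdf15 at 1.33 and past it for labelled knockout training. With log2 Myl7 as a covariate wild-type training gave 160 down, with 256 shared, and Gdf15 was at 0.96 and past the threshold.

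With an estimated correlation camera called 0 of 29 gene lists and 0 of 13 marker lists in the sedentary genotype (18 and 3 with the preset, 6 and 1 at an unadjusted p below 0.05), 0 and 0 for wild-type training (15 and 9, 3 and 0), 0 and 0 for labelled knockout training (21 and 4, 13 and 3), 5 and 0 for the trained genotype (20 and 4, 12 and 2) and 0 and 0 for the interaction (20 and 3, 6 and 1). By fry, which tests a list against no change and not against other genes, 17 gene and 1 marker lists passed in the sedentary genotype, 12 and 2 for wild-type training, 21 and 5 for labelled knockout training, 23 and 5 for the trained genotype and 13 and 3 for the interaction.

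Without 1 library the ranges were 580 to 1370 up and 551 to 1435 down (sedentary genotype), 94 to 1051 and 33 to 1260 (wild-type training), 1242 to 1678 and 1870 to 2300 (labelled knockout training), 1355 to 1752 and 1777 to 2112 (trained genotype) and 119 to 611 and 343 to 1087 (interaction), with 71 to 907 genes shared by the training and 784 to 1139 by the genotype comparisons. Ppargc1a ranged from 0.80 to 0.97 (sedentary genotype), 0.20 to 0.46 (wild-type training), -0.09 to 0.07 (labelled knockout training), 0.42 to 0.67 (trained genotype) and -0.47 to -0.21 (interaction), and Gdf15 from 0.01 to 0.39, 0.49 to 0.97 and 0.27 to 0.76 for the training comparisons and the interaction. On simulated data 64% of 1.5-fold and 90% of 2-fold changes were recovered for labelled knockout training, and 34% and 66% for the interaction, so small interactions can be missed at this depth and number of mice. Unchanged genes called were 5 and 2. The simulated genes varied independently, and 50 per fold were changed, in trained labelled knockout hearts only. Labelled knockout training called 3892 genes in the real data, so the simulated rates may not carry over.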

Other observations

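The test of genes near Ppargc1a was chosen before its result was seen, and the fits without libraries of high Myl7 and with log2 Myl7 as a covariate after. Mitochondrial chaperones and proteases fell in 12 of 17 with training in labelled knockout hearts (median -0.39, camera adjusted p = 3.7e-07, adjusted p = 0.0715 with an estimated correlation) and were lower in 11 of 17 in the trained genotype comparison (median -0.39, camera adjusted p = 3.0e-07, adjusted p = 0.0576 with an estimated correlation). Mitochondrial dynamics and mitophagy genes fell in 8 of 17 with that training (median -0.28, camera adjusted p = 4.0e-04, adjusted p = 0.0715 with an estimated correlation). Antioxidant genes went both ways there, with 5 of 27 up and 12 down (camera adjusted p = 0.170, adjusted p = 0.508 with an estimated correlation), and in sedentary labelled knockout hearts 6 were up and 4 down, among them Sod2 (-0.67). Glucose uptake and glycolysis genes had 4 of 23 up and 10 down with training in labelled knockout hearts, at a median of -0.22 that was 0.05 after TPM scaling (camera adjusted p = 0.0262, adjusted p = 0.284 with an estimated correlation). Camera did not call that list without the 4 libraries with atrial transcripts (adjusted p = 0.227) or with log2 Myl7 as a covariate (0.0579), and Pfkfb1, a kinase and phosphatase of glycolytic control, was at -1.37 in the sedentary genotype comparison. Interferon-stimulated genes rose in 4 of 23 with that training (camera adjusted p = 0.00545, adjusted p = 0.478 with an estimated correlation). Endoplasmic reticulum stress genes had 3 of 20 up and 1 down (camera adjusted p = 0.236, adjusted p = 0.675 with an estimated correlation), and growth factor and hypertrophic signalling genes 5 of 28 up and 3 down, with Igf1 at 1.04 (camera adjusted p = 0.279, adjusted p = 0.603 with an estimated correlation).

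With training in labelled knockout hearts epicardial and mesothelial markers rose in 2 of 8 (median 0.89, camera adjusted p = 0.0256, adjusted p = 0.570 with an estimated correlation), and camera no longer called the list without the 4 libraries with atrial transcripts (adjusted p = 0.158). The marker lists that follow were not called by camera. Endocardial and lymphatic markers rose in 2 of 8 (camera adjusted p = 0.0831, adjusted p = 0.384 with an estimated correlation). Pericyte and smooth muscle markers had 2 of 9 up and 1 down (camera adjusted p = 0.397, adjusted p = 0.650 with an estimated correlation), Schwann and neural markers 1 of 7 up (camera adjusted p = 0.149, adjusted p = 0.650 with an estimated correlation) and erythroid markers 1 of 8 down (camera adjusted p = 0.155, adjusted p = 0.650 with an estimated correlation). Neutrophil and monocyte, lymphocyte, and thymus and lung markers had 2, 2 and 1 measured members and were not tested, with medians of 0.47, 0.27 and -0.07.

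DNA of another strain around the targeted gene could change genes near it. Of 38 tested genes within 10 Mb of Ppargc1a 3 (7.89%) were called in the same direction in both genotype comparisons, against 7.59% of the other genes. So this window holds few of the genotype calls. The 3 were Lgi2 (1.17 in sedentary and 1.62 in trained mice), Rab28 (-0.36 and -0.39) and Gm45495 (-0.69 and -0.79). Lgi2 and Gm45495 lie nearer to Ppargc1a than Rab28. A share that rests on 3 genes cannot decide whether such DNA changed genes near the targeted gene.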
